A study of Homo sapiens with 2 samples.

How the data were processed

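RNA-seq of 2 libraries of human MCF-10A cells was analysed, 1 labelled as treated with DMSO and 1 as treated with 1 µM DEHP for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the KAPA mRNA HyperPrep kit. The authors deposited 1 table of raw counts per gene, whole numbers with Ensembl gene identifiers and no normalisation. The submitters' processing notes name the GRCh38 build. The aligner, the counting tool, the annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Counts of near-identical paralogs, of genes with pseudogene copies and of overlapping or antisense genes can therefore hold each other's reads.

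The table has 1 column per library and 0 columns of other samples. The DEHP column was matched to the DEHP sample by name. The other column is named for parental cells, and it was matched to the DMSO sample because the extraction protocol sets parental cells against DEHP-treated ones. If parental meant cells without solvent, the comparison would include the solvent.

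Of 58884 gene identifiers, 58472 were matched to a current symbol and 58611 to GENCODE 29, which supplied gene types, GRCh38 coordinates and the length and GC content of each gene's longest transcript. At least 1 count in either library was found for 28140 genes, and 12676 had a mean scaled count of at least 30, of which 11352 (89.6%) were protein-coding. Length and GC content were known for 99.9% of these.

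Library sizes were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, which gave factors of 1.004 for the DMSO library and 0.996 for the DEHP library. With 1 library per group there are no residual degrees of freedom, so no model was fitted and no p-value was computed. The ratio of scaled counts was given an exact 95% Clopper-Pearson interval from the binomial split of each gene's 2 counts (scipy 1.17.1). Reads without molecular identifiers are not independent molecules, so these intervals and the floor of 3 counts for a library at 0 cover counting error only. A count of 0 was replaced by 0.5 in ratios. A gene was counted as higher or lower when its mean scaled count was at least 30, its ratio at least 2-fold and its interval excluded 1. The number expected from counting error alone came from 100 binomial draws.

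Of 45 gene lists fixed before the data were examined, 43 had at least 5 members with a mean scaled count of at least 30. Each list's median log2 ratio was given as a percentile among 10000 random lists of the same size drawn with replacement within 20 bins of mean count. A list was said to stand apart when its median lay outside the central 95% of those lists. Within lists, members were counted at a ratio of at least 1.5-fold with an interval excluding 1. Coordinates are from GENCODE 29.

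Genes were named by a rule fixed before the data were examined. It took the 10 genes with the highest and the 10 with the lowest ratio by the interval bound nearest 1, leaving out genes without a symbol and pseudogenes. It took up to 4 members of each list by the same bound among those at least 1.5-fold apart, or the 2 most abundant where there were none. It always took ESR1, AHR, PPARA, PPARD, PPARG, CYP1A1, CYP1B1, ANGPTL4, PDK4, HMOX1, CDKN1A, MKI67 and MYC, and the 3 most abundant basal, luminal, fibroblast, immune and endothelial markers. Some genes it took are not reported here. Genes outside it are said to be chosen after their values were seen.

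Alternatives were DESeq2 1.42.0 size factors, total count and upper-quartile scaling, no count minimum or a minimum of 100, a ratio of 1.5 or an interval bound of at least 2-fold, a prior count of 5, removal of loess trends on GC content and length (statsmodels 0.14.6, fraction 0.3), and the mean in place of the median of a list. Scaling to the total without mitochondrially encoded genes was added after seeing the data. The median log2 ratio of all tested genes moved by less than 0.1 under every scaling, from -0.05 with DESeq2 size factors to 0.04 without mitochondrial genes.

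The steps were tested on simulated counts drawn from the mean counts and library sizes of this comparison, with 12705 genes past the minimum and 200 made to differ. All 50 genes made 4-fold higher and all 50 made 4-fold lower were counted. Of those made exactly 2-fold different, which lie on the threshold, 25 of 50 higher and 30 of 50 lower ones were counted, and 0 genes were counted in the wrong direction. Of 12505 unchanged genes 6 were counted, and the interval held a ratio of 1 for 95.6%. The draws held counting error only, the error the interval is built for. These rates therefore do not cover differences between cultures or libraries. A list of 20 genes made 2-fold higher lay at percentile 100, and 9 of 200 lists of unchanged genes stood apart.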

Results

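MCF-10A is an immortalised, non-tumorigenic human breast epithelial cell line. Its RNA was sequenced after 24 h with 1 µM di(2-ethylhexyl) phthalate (DEHP), a plasticiser of polyvinyl chloride, or with the solvent dimethyl sulfoxide (DMSO). The labels give 2 libraries, 1 per condition, and the design asks which genes differ in expression under DEHP. The sample labels name MCF-10A, whereas the series title speaks of cancer cells, and the deposited table names its control column for parental cells. That column was taken as the DMSO library. Gene counts summed to 17751096 in the DMSO library and 16490852 in the DEHP library, with 25334 and 25038 genes detected. With 1 library per condition there is no replicate check, so each ratio compares these 2 libraries, not the conditions, and no p-value is given. Intervals are 95% exact (Clopper-Pearson) and cover counting error only. Treatment, culture, library preparation and any sequencing batch differ together.

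Relative to the DMSO library, the DEHP library held more mRNA of genes for cholesterol and fatty acid synthesis and for cell division. By list medians it held less mRNA of p53 target genes, unfolded protein response genes, cytosolic ribosomal protein genes, basement membrane, hemidesmosome and integrin genes, and clock genes. Of 12676 genes with a mean scaled count of at least 30, 557 were at least 2-fold higher and 452 at least 2-fold lower, with an interval excluding 1. These 1009 genes made up 7.96% of those tested. Counting error alone gave on average 1.9 genes higher and 2.56 lower in 100 simulated draws, and never more than 9 in all. Among 3780 genes with a mean count of at least 1000, the log2 ratios had an SD of 0.47, against 0.05 from counting error.

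**Figure D1:**
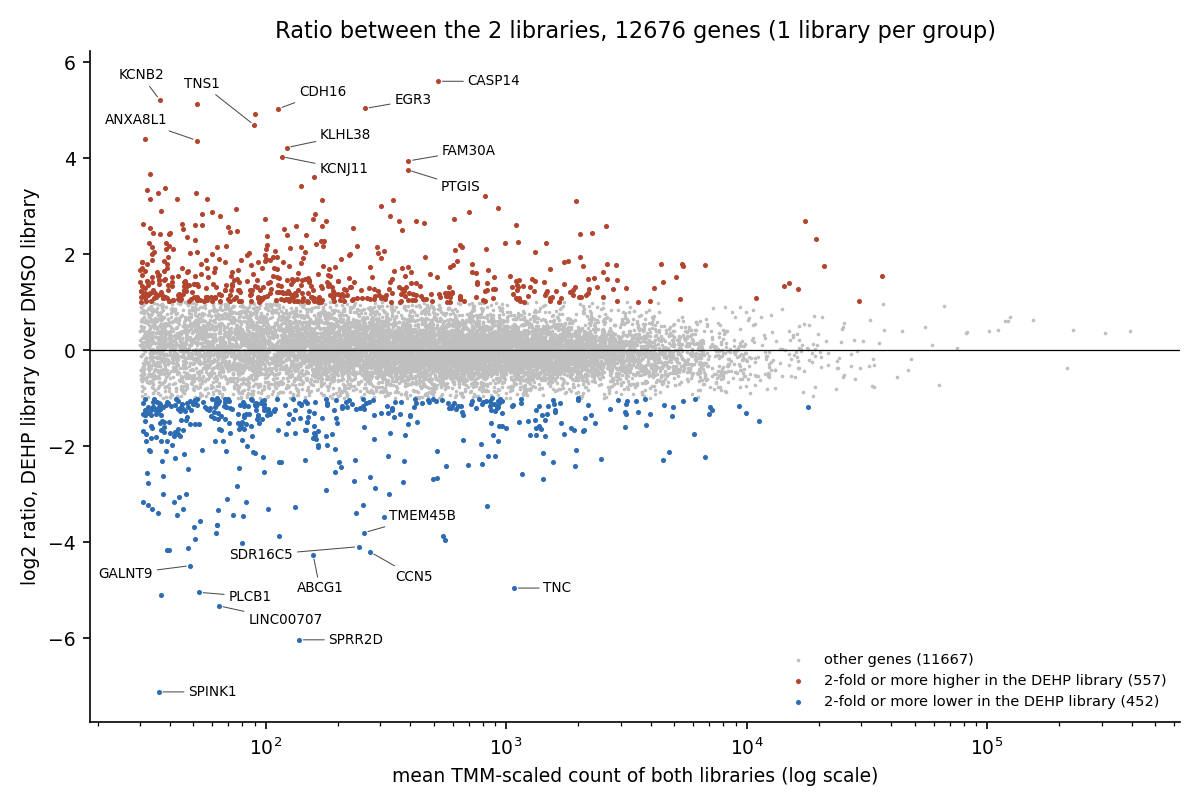
Mean TMM-scaled count of each of 12676 genes (x axis, log scale) against the log2 ratio of the DEHP library over the DMSO library (y axis). Red points mark the 557 genes at least 2-fold higher and blue points the 452 at least 2-fold lower in the DEHP library, and labels mark the 10 genes named at each end. SPINK1, with 0 counts in the DEHP library, is drawn with 0.5 in place of 0.

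The largest ratio upwards was that of CASP14, a caspase of epidermal cornification (ENSG00000105141, GRCh38 chromosome 19, 15049384 to 15058293). It had 22 counts in the DMSO library and 983 in the DEHP library, a 48.5-fold ratio with an interval of 31.8 to 77.7. The transcription factor EGR3 (16 and 483 counts) was 32.7-fold higher, the kidney cadherin CDH16 (7 and 210 counts) 32.5-fold and the focal adhesion gene TNS1 25.7-fold. The prostacyclin synthase gene PTGIS was 13.5-fold higher (56 and 697 counts), the potassium channel gene KCNJ11 16.3-fold, KLHL38 18.6-fold and the RNA gene FAM30A 15.4-fold. KCNB2 rested on 2 and 68 counts, which gave a ratio of 36.9 with an interval of 9.82 to 311. ANXA8L1 was 20.6-fold higher, but its near-identical paralogs can share its reads, so that value is uncertain.

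At the other end, SPRR2D, a cornified envelope precursor (ENSG00000163216, chromosome 1, 153039725 to 153041931), had 283 counts in the DMSO library and 4 in the DEHP library. It was 65.2-fold lower with an interval of 25.2 to 241, and reads that other SPRR2 genes can share leave it uncertain. TNC, the matrix glycoprotein tenascin C (ENSG00000041982, chromosome 9, 115019578 to 115118257), had 2179 and 65 counts and was 30.9-fold lower (interval 24.2 to 40.2). The trypsin inhibitor gene SPINK1 had 75 and 0 counts, at least 23.1-fold lower against a floor of 3 counts in the DEHP library, which takes the 75 as exact, and its interval reaches down to 18.3-fold. The sterol exporter gene ABCG1 was 19.2-fold lower (312 and 15 counts), CCN5 18.4-fold, the retinol dehydrogenase gene SDR16C5 17-fold and TMEM45B 13.9-fold. The phospholipase gene PLCB1 (107 and 3 counts) had a ratio 32.9-fold lower (interval 11 to 162), LINC00707 (130 and 3 counts) 40.0-fold lower (interval 13.4 to 196) and GALNT9 (97 and 4 counts) 22.4-fold lower.

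**Figure D2:**
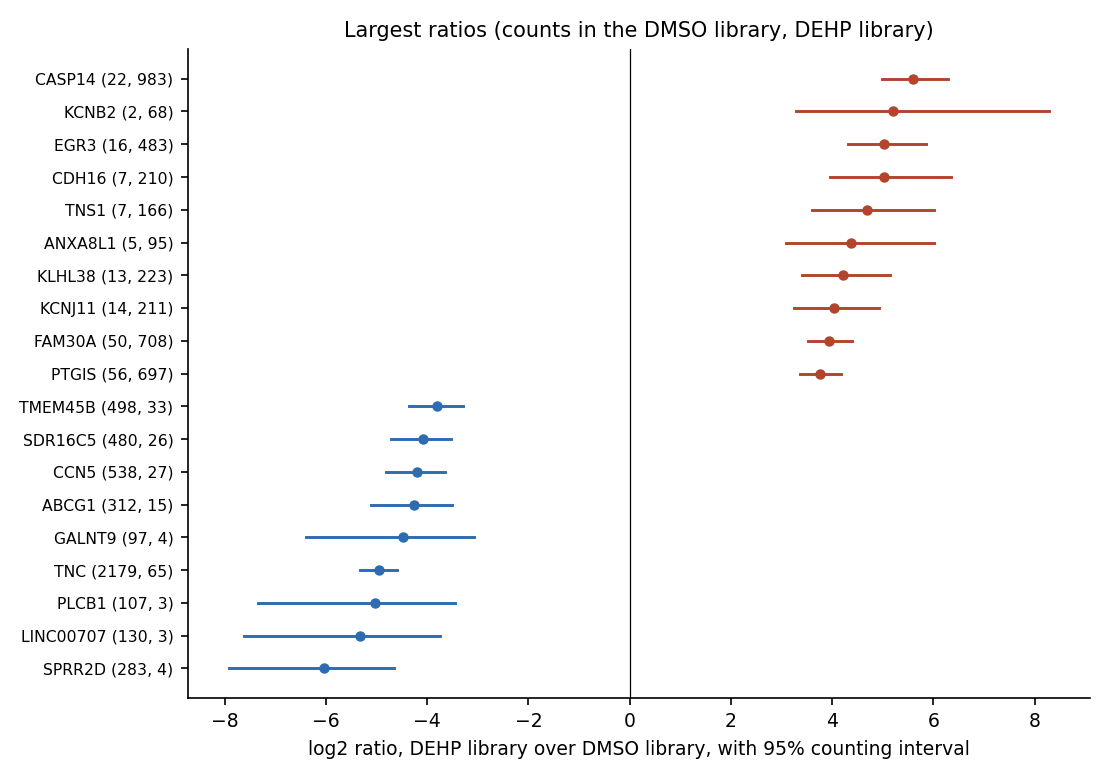
Log2 ratio of the DEHP library over the DMSO library (x axis) with its 95% exact counting interval (line) for 19 of the 20 genes at the ends of the ranking, with both counts beside each name. SPINK1 is left out because its interval has no finite lower end on this axis. All 19 intervals lie on one side of 0.

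Gene lists were fixed before the data were examined, and each list's median log2 ratio was placed among those of 10000 random lists matched on expression. Of 43 lists with at least 5 tested members, 9 lay above the central 95% of random lists and 10 below it, where 2.15 in all would by chance. Random lists treat genes as independent, which genes of a pathway are not, so the percentiles describe these libraries only.

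Genes of cholesterol synthesis and uptake were higher throughout. All 24 tested members had a ratio above 1 and 18 were at least 1.5-fold higher, with a median log2 ratio of 0.88 (percentile 100). INSIG1, the sterol-regulated anchor of the SREBP pathway (ENSG00000186480), was 3.83-fold higher (interval 3.56 to 4.14), MVD 3.10-fold, ACAT2 2.66-fold and HMGCS1 2.51-fold. Of 15 genes of fatty acid and triglyceride synthesis, 8 were at least 1.5-fold higher and 0 as much lower (median 0.60, percentile 100). FASN, the fatty acid synthase gene (ENSG00000169710), had 10035 and 31177 counts, 3.37-fold higher (interval 3.29 to 3.45), and SCD was 2.94-fold, ACSS2 2.69-fold and LPIN1 2.13-fold higher.

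Cell-division genes were higher on balance. All 29 tested genes of G2 and mitosis had a ratio above 1, and 15 were at least 1.5-fold higher (median 0.79, percentile 100). KIF20A, a kinesin of cytokinesis (ENSG00000112984), was 3.81-fold higher (131 and 460 counts, interval 3.13 to 4.66), CENPE 2.84-fold, DLGAP5 2.60-fold and the proliferation marker MKI67 2.40-fold (interval 2.19 to 2.63). Of 25 genes of S phase and DNA replication, 10 were at least 1.5-fold higher and 0 as much lower (median 0.49, percentile 99.95), among them RRM2 at 1.90-fold, CDT1 at 1.85-fold and MCM4 at 1.65-fold, while 7 had a ratio below 1. With a minimum mean count of 100 that median was 0.31, at percentile 98. Of 26 p53 target genes, 11 were at least 1.5-fold lower and 2 as much higher (median -0.46, percentile 0.01). GDF15, a stress-induced cytokine (ENSG00000130513), had 7804 and 1469 counts and was 4.90-fold lower (interval 4.63 to 5.18). BTG2 was 2.31-fold lower, AEN 2.14-fold and the cyclin-dependent kinase inhibitor gene CDKN1A 1.83-fold (interval 1.77 to 1.89), while PLK3 was 2.24-fold higher. MYC had a ratio of 1.00 (interval 0.95 to 1.06). Replication-dependent histone genes, which mostly lack poly(A) tails, had 7 tested members and a median of -0.40 (percentile 3.26), with H4C8 2.21-fold and H2BC5 1.89-fold lower, and reads that copies can share leave these uncertain. RN7SL1 and RN7SL2, 2 other RNA genes without such tails, chosen after their values were seen, together took 0.011% and 0.0026% of counts, so less carry-over of such RNA into the DEHP library stays open.

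Target genes of receptors through which phthalates have been studied were examined next. The median of 18 PPAR target genes was -0.22 (percentile 4.94), with 2 members at least 1.5-fold higher and 3 as much lower, but their mean was -0.005 (percentile 56.3). ACADM was 1.57-fold higher, ECH1 1.62-fold and SLC25A20 1.53-fold lower, and ACOT1 4.48-fold higher from 15 and 62 counts that its paralog ACOT2 can share. The PPAR targets ANGPTL4 and PDK4 were 1.75-fold lower and 1.46-fold higher. The receptor genes PPARD and PPARG were 1.57-fold and 1.53-fold lower, and for PPARA the interval spanned 1 (0.975 to 1.14). The 7 tested aryl hydrocarbon receptor target genes had a median of -0.24 (percentile 14.2) and a mean of -0.38 (percentile 4.47), with LRAT 2.16-fold and SLC7A5 1.92-fold lower. CYP1A1, the classical target of that receptor, had 10 and 5 counts, too few to show a difference, CYP1B1 was 1.13-fold higher, and the receptor gene AHR was 1.09-fold lower (interval 1.04 to 1.15).

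Of 13 estrogen response genes, 3 were at least 1.5-fold higher and 3 as much lower, and their median of -0.31 lay at percentile 1.66. PDZK1 was 10.7-fold higher (25 and 246 counts) and GREB1 2.70-fold higher, whereas CCND1, the cyclin D1 gene (ENSG00000110092), was 4.34-fold lower (8043 and 1709 counts) and the EGF receptor ligand gene AREG 3.43-fold lower. Taken as a mean, -0.06, the list lay at percentile 34.5. ESR1, the estrogen receptor gene, had 314 and 377 counts, 1.30-fold higher (interval 1.12 to 1.52). Among 19 tested nuclear receptor genes the median was -0.08 (percentile 28.2), or 0.06 without a count minimum, with the coactivator gene PPARGC1B 1.90-fold and RXRA 1.59-fold higher, and RARA 1.80-fold and VDR 1.6-fold lower. The median of 12 glucocorticoid response genes was 0.26 (percentile 98.9), or 0.43 (percentile 99.96) with a minimum mean count of 100, which leaves out ANGPTL4. But only ZBTB16 was at least 1.5-fold higher (1.72-fold) and only ANGPTL4 as much lower, and the mean of the 12, 0.08, lay at percentile 80.8. The 15 xenobiotic enzymes and ABC transporters had a median of -0.27 (percentile 4.42) but a mean of -0.13 (percentile 23.5). Of these, the exporter gene ABCG2 was 4.07-fold and CES2 1.67-fold higher, and GSTA4 2.52-fold and ABCC1 1.61-fold lower.

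Unfolded protein response genes of the endoplasmic reticulum were lower on balance. Of 19 such genes, 18 had a ratio below 1, 6 were at least 1.5-fold lower and 0 as much higher (median -0.39, percentile 0.09). HSPA5, which encodes the chaperone BiP, had 14745 and 5530 counts, 2.46-fold lower (interval 2.38 to 2.54), and HYOU1 was 2.04-fold, SEC61B 1.93-fold and SEL1L 1.84-fold lower. Of 26 ATF4 and amino acid response genes, 6 were at least 1.5-fold lower and 1 as much higher (median -0.20, percentile 4.66). DDIT3 was 2.27-fold and the amino acid transporter subunit gene SLC3A2 2.25-fold lower, while VLDLR was 4.44-fold higher. The 21 NRF2 target genes had a median of -0.07 (percentile 36.8), or -0.18 (percentile 7.7) without GC and length trends. OSGIN1 was 3.31-fold lower, and AKR1C1, AKR1C2 and AKR1C3, similar copies that can share reads, were 2.40-fold, 2.40-fold and 2.37-fold higher. HMOX1 was 1.64-fold lower (314 and 177 counts). The 17 heat shock protein genes had a median of -0.02 (percentile 64.1), whose sign changed with the scaling and differed from that of their mean, with CRYAB 2.04-fold and HSPB1 1.78-fold higher and STIP1 1.75-fold lower.

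Cytosolic ribosomal protein mRNAs were lower in 50 of 51 cases, by a narrow range around a median of -0.43 (percentile 0.0). Only 6 were at least 1.5-fold lower, led by RPS19 (1.68-fold), RPS12 (1.62-fold), RPL35 (1.58-fold) and RPL27 (1.57-fold). The list took 3.87% of counts in the DMSO library and 2.89% in the DEHP library. All 13 mitochondrially encoded mRNAs were higher (median 0.49, percentile 99.99), with MT-CYB at 1.61-fold, MT-ATP8 at 1.57-fold, MT-CO3 at 1.54-fold and MT-ATP6 at 1.53-fold. Mitochondrially encoded genes took 9.15% (interval 9.13% to 9.16%) and 12.5% (interval 12.5% to 12.6%) of counts. The 40 nuclear-encoded oxidative phosphorylation genes had a median of -0.03 (percentile 54.4), whose sign changed with the scaling, and 38 of them lay within 1.5-fold, the exceptions being ATP5MC1 (1.82-fold lower) and NDUFA13 (1.95-fold lower).

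Hypoxia response genes were lower on balance, with 6 of 21 at least 1.5-fold lower and 2 as much higher (median -0.33, percentile 0.17). LOX was 2.60-fold, NDRG1 2.55-fold, the glucose transporter gene SLC2A1 2.01-fold and P4HA2 1.81-fold lower. The 19 glycolysis genes had a median of -0.29 (percentile 2.94). It was -0.17 (percentile 13.2) without a count minimum, and their mean was -0.20 (percentile 10.6). PFKP, a phosphofructokinase, was 3.36-fold lower (9688 and 2660 counts), SLC16A1 was 1.89-fold lower and ALDOC 1.87-fold higher.

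Basement membrane, hemidesmosome and integrin genes were lower on balance, 9 of 23 by at least 1.5-fold against 1 as much higher (median -0.49, percentile 0.01). The collagen genes COL4A1 and COL4A2 were 3.42-fold and 2.44-fold lower, and the integrin genes ITGA5 and ITGA6 2.66-fold and 2.51-fold lower. Of 16 mesenchymal genes (median -0.30, percentile 1.00), 6 were at least 1.5-fold lower, among them MMP2 at 17.3-fold (94 and 5 counts) and the transcription factor SNAI2 at 5.2-fold. S100A4 went the other way, 8.67-fold higher (419 and 3350 counts, interval 7.83 to 9.62). With a minimum mean count of 100 the mesenchymal median of -0.28 lay at percentile 2.78. Of 17 matrix protease and inhibitor genes (median -0.03, percentile 53.4, sign dependent on the scaling), the kallikrein genes KLK7 and KLK5 were 2.43-fold and 2.04-fold higher, and SERPINE2 and TIMP3 7.97-fold and 3.19-fold lower. The 24 epithelial junction genes had a median of 0.01 (percentile 80.3), which also changed sign with the scaling, with ESRP2 1.57-fold higher and OCLN 1.85-fold lower.

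The keratins diverged. KRT14, a basal keratin (ENSG00000186847), was 6.08-fold higher (323 and 1810 counts), KRT16 4.99-fold, KRT17 2.65-fold and KRT15 1.90-fold, and KRT5 (29638 and 31007 counts) was 1.13-fold higher, where reads that related keratins can share leave single values uncertain. Of the 14 basal and myoepithelial markers, 5 were at least 1.5-fold higher and 6 as much lower, with a median of 0.19 at percentile 97.7. That percentile was 94.6 once GC content and length trends were removed and 96.8 without a count minimum. Of 12 luminal markers (median 0.29, percentile 98.9), 4 were at least 1.5-fold higher, among them PRLR (5.34-fold from 13 and 64 counts), ERBB3 (2.14-fold) and MUC1 (1.87-fold), while KRT18 was 1.64-fold lower and KRT8 1.07-fold higher. The luminal list lay at percentile 80.8 without a count minimum and 94.9 with a minimum of 100. Only 8 of the 31 cornified envelope and squamous genes were tested (median -0.79, percentile 0.02). Besides SPRR2D, KLF4 was 1.91-fold and KRT10 1.70-fold lower, and IVL, the involucrin gene, was 2.5-fold higher. With a minimum mean count of 100 that list's median was -0.14, at percentile 20.7. The 9 tested stem and progenitor markers had a median of -0.32 (percentile 7.18), with CD24 2.51-fold higher and PROCR 2.28-fold lower. Their median was -0.16 (percentile 30.4) with a minimum mean count of 100 and -0.20 (percentile 22.3) without a minimum.

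Genes of growth factor signalling went both ways. In the EGF family (12 genes, median -0.29, percentile 3.47) 2 members were at least 1.5-fold higher and 5 as much lower, and the ligand genes NRG1, AREG, HBEGF and TGFA were 3.92-fold, 3.43-fold, 2.87-fold and 2.23-fold lower. As a mean, -0.40, that list lay at percentile 1.66, but with a minimum mean count of 100 its median of -0.07 lay at percentile 43.7. Of 28 immediate early and ERK feedback genes (median 0.03, percentile 78.8, sign dependent on the scaling), FOSB was 1.82-fold higher beside EGR3, and IER3 and ETV5 were 2.02-fold and 1.98-fold lower. Of 23 TGF-beta response genes (median -0.10, percentile 16.6), 5 were at least 1.5-fold higher and 7 as much lower, with ID1 4.63-fold, TGFBI 4.21-fold and TGFB2 2.25-fold lower. Among 21 YAP and TEAD target genes (median -0.09, percentile 26.2), the ectonucleotidase gene NT5E was 6.37-fold, the receptor kinase gene AXL 4.85-fold and IGFBP3 2.48-fold lower, and GADD45B 2.75-fold higher. The 14 Wnt pathway genes had a median of -0.13 (percentile 19.3), or 0.004 without a count minimum, with WNT4 4.42-fold higher and RNF43 and WNT7B 2.73-fold and 1.86-fold lower. In the Notch pathway (11 genes, median -0.05, percentile 39.9) JAG1, a Notch ligand, was 5.94-fold lower (2067 and 321 counts), HEY1 3.50-fold and NOTCH3 2.01-fold. As means, the YAP and Notch lists lay at percentiles 0.57 and 1.4.

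NF-kB and inflammatory cytokine genes were lower on balance. Of 18 tested, 6 were at least 1.5-fold lower and 1 as much higher (median -0.44, percentile 0.04). The chemokine gene CXCL2 was 7.95-fold lower (69 and 8 counts), IL1A 4.59-fold, SAA2 3.45-fold and the complement gene C3 2.77-fold (17250 and 5746 counts), and SAA2 can share reads with SAA1. With a minimum mean count of 100 the median was -0.15, at percentile 15.7. The 17 interferon response genes had a median of -0.05 (percentile 30), which depended on the count minimum (-0.34 at percentile 2.71 without one, 0.04 at percentile 58.8 with 100), with EPSTI1 2.5-fold higher and ISG15, IFIH1 and IFIT1 3.23-fold, 2.38-fold and 1.89-fold lower. Among 14 antigen presentation genes (median -0.15, percentile 13), HLA-B, whose reads related HLA genes can share, was 2.01-fold and ERAP2 1.52-fold lower, and NLRC5 1.6-fold higher.

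Circadian clock genes were lower on balance, 6 of 15 by at least 1.5-fold against 2 as much higher (median -0.56, percentile 0.0). NR1D1, the clock repressor REV-ERB alpha (ENSG00000126368), had 893 and 128 counts, 6.43-fold lower (interval 5.34 to 7.80), TEF was 1.80-fold and NR1D2 1.74-fold lower, and BHLHE41 was 2.78-fold higher. Of 30 lysosome and autophagy genes (median 0.16, percentile 98.5), 6 were at least 1.5-fold higher and 3 as much lower. GPNMB was 7.96-fold higher, MCOLN1 1.95-fold and the kinase gene ULK1 1.73-fold. The 5 tested metallothionein and metal response genes had a median of 0.49 (percentile 97.4), with MT1E and MT1X, which can share reads with other copies, 2.85-fold and 2.10-fold higher and SLC30A1 1.53-fold lower. Of 23 DNA methylation, chromatin and histone deacetylase genes (median -0.08, percentile 22.4), 20 lay within 1.5-fold, and HDAC5 and TET1 were 1.67-fold and 1.55-fold higher and HDAC4 1.67-fold lower.

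Markers of other cell types gave no common direction. The 5 tested fibroblast and stromal markers had a median of 0.22 (percentile 79.3), with FBLN1 and MGP 1.45-fold and 1.78-fold higher and FAP at 225 and 242 counts. Only 2 immune markers were tested, CD14 (4.61-fold lower, 1435 and 287 counts) and CSF1R (2.90-fold higher), and FCER1G had 8 and 7 counts. Of 4 endothelial markers, PECAM1 (3.47-fold, 2502 and 8016 counts) and KDR (1.87-fold) were higher and EGFL7 (2.55-fold) and CDH5 (1.95-fold) lower, so that their median of -0.03 and mean of 0.10 differed in sign.

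**Figure D3:**
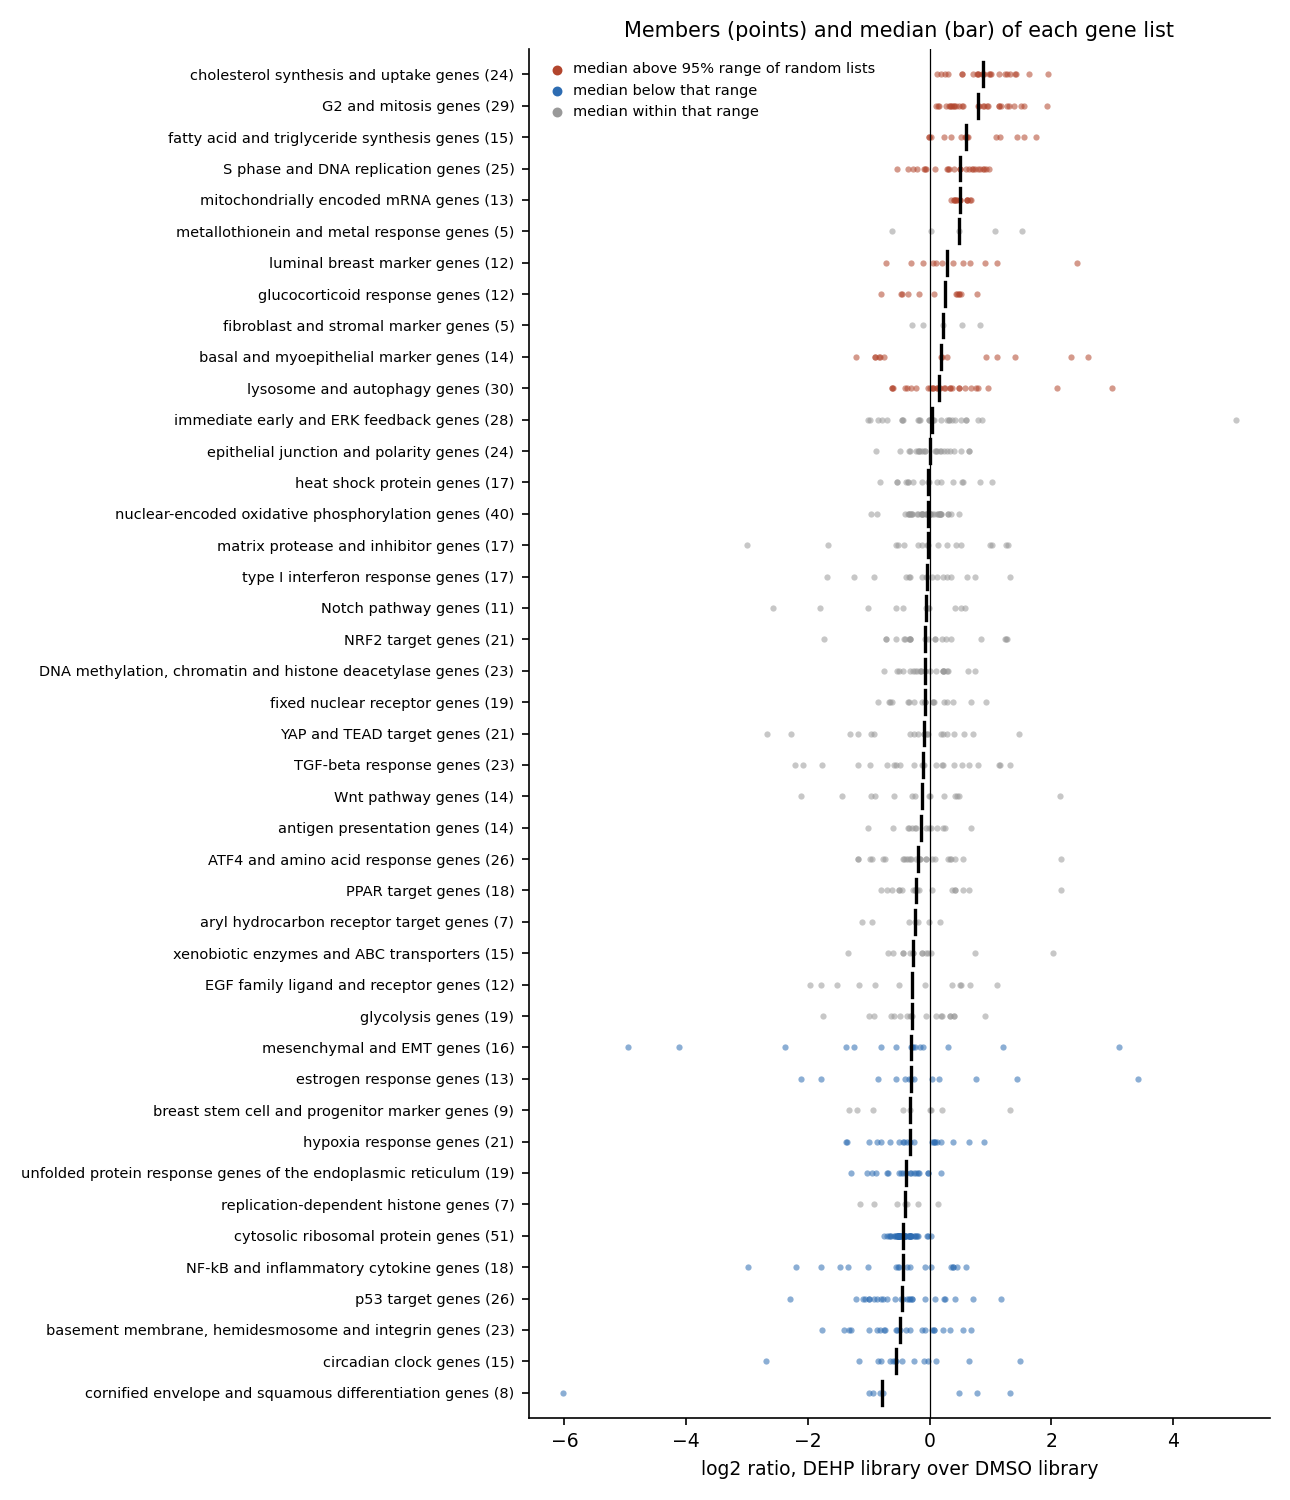
Log2 ratio of the DEHP library over the DMSO library (x axis) of each tested member (points) and the median (bar) of the 43 gene lists with at least 5 tested members, whose number stands beside each name. Colours show whether the median lay above the central 95% of expression-matched random lists (red, 9 lists), below it (blue, 10 lists) or within it (grey, 24 lists). Cholesterol synthesis stands at the top with a median of 0.88 and cornified envelope genes at the bottom with -0.79.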

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

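All alternatives here were planned before the data were examined, except scaling to the total without mitochondrially encoded genes. The counts of genes at least 2-fold higher and lower, 557 and 452, stayed within 1.5 times under every scaling. They were 502 and 506 with DESeq2 size factors, 545 and 464 by total count, 516 and 491 by upper quartile, and 623 and 417 without mitochondrial genes. A prior count of 5 gave 492 and 414, and removing GC and length trends 548 and 450. The count minimum and the criterion mattered more, as follows from testing more or fewer genes and from the threshold itself. There were 1220 and 1039 genes without a minimum, 335 and 243 with a minimum of 100, 1478 and 1265 at a ratio of 1.5, and 273 and 226 when the interval bound had to reach 2-fold.

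The 19 lists that stood apart did so under all 4 other scalings. That follows from the method, because a scaling moves every gene and the random lists alike. None of the 19 changed sign under any alternative. Basal markers fell inside the random range without a minimum (median 0.18) and without GC and length trends (0.12), luminal markers without a minimum (0.10) and with a minimum of 100 (0.195). The minimum of 100 also moved mesenchymal (-0.28), cornified envelope (-0.14) and NF-kB genes (-0.15) inside it, with fewer members tested. Taken as means, estrogen (-0.063) and glucocorticoid response genes (0.081) fell inside, and EGF family (-0.40), YAP (-0.31) and Notch genes (-0.45) outside. The S phase median was 0.31 with a minimum of 100, still outside. Notch genes also stood apart without a minimum (-0.50), and metallothionein genes without GC and length trends (0.58) or without mitochondrial genes (0.53). Of the other lists, the medians of Wnt (0.004) and nuclear receptor genes (0.06) changed sign without a minimum and that of interferon response genes (0.04) with a minimum of 100. That of epithelial junction genes did so with a minimum of 100 (-0.07) and without GC and length trends (-0.07), and those of immediate early (-0.01) and oxidative phosphorylation genes (0.04) without these trends. The cause was not tested for these.

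Of 185 tested genes that the naming rule took, none that was at least 1.5-fold apart changed sign. The ratio left its counting interval for 19 of the 185 with DESeq2 size factors, 17 without GC and length trends, 10 by upper quartile, and 1 each by total count and with a prior count of 5. Of the 175 at least 1.5-fold apart, MT-ATP6 and MT-CO3 came under 1.5-fold with DESeq2 size factors, MT-ATP6 by upper quartile, ERAP2 and TET1 with a prior count of 5, and ESRP2, PPARG, RPS12, RXRA and SLC25A20 without GC and length trends. The log2 ratios of the 185 moved by at most 0.05 with DESeq2 size factors and 0.17 without GC and length trends, and by 3.17 for SPINK1 with a prior count of 5. The median absolute log2 ratio of genes with a mean of at least 1000 was 0.24 by either TMM or total count. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits genes near 30 counts most: between 30 and 100 the SD of log2 ratios from counting error was 0.28, against 0.05 above 1000.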

Other observations

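In this part, the tests of the growth state of the culture and of RNA from other cell types, and the scaling without mitochondrial genes, were chosen only after the results were seen. The correlation of ratios with GC content and the medians per chromosome had also been seen before the tests on them were fixed. Genes named here outside the rule were chosen after their values were seen.

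FBXO32, which encodes the ubiquitin ligase atrogin-1, was among the most abundant genes with a large difference, with 4892 and 28999 counts (6.43-fold higher in the DEHP library, interval 6.24 to 6.63). The fibroblast growth factor receptor genes went opposite ways, FGFR1 (2421 and 507 counts) 4.40-fold lower and FGFR2 (15 and 84 counts) 6.07-fold higher. A run of neighbouring pseudogenes on chromosome 21 was lower together. CYP4F29P (13843133 to 13848364) had 1093 and 65 counts, ANKRD20A11P (13909574 to 13980437) 1063 and 67, and SNX18P13 (13905960 to 13906488) 74 and 2. Related copies elsewhere can share their reads. The signal recognition particle RNA genes RN7SL1 and RN7SL2 were 4.94-fold and 3.86-fold lower, although RNA without poly(A) tails is only carried over in such libraries.

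Genes often used to recognise MCF-10A gave a mixed picture in both libraries. CDKN2A and CDKN2B, whose locus is known to be deleted in MCF-10A, had 0 counts in each library (a 0 allows up to 3), and their neighbour MTAP had 7 and 3. VIM, the vimentin gene, which MCF-10A is commonly described as expressing, had 38 and 1 counts, and TP63, the basal transcription factor gene, 85 and 169. Of the other marker genes, the luminal marker ESR1 had 314 and 377 counts and the endothelial marker PECAM1 2502 and 8016. No reference profile of the line was used here, so its identity was not tested.

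Sterol, fatty acid and cell-division genes were higher in the DEHP library in 4 lists. Ratios followed GC content and length only weakly (Spearman 0.10 and 0.03), and removing both trends moved the genes named by the rule by at most 0.17. After that removal the lowest of the 4 medians was 0.41. Trends this weak could account for little of the 4 medians, so the 0.41 follows from their size and is no separate test. Over the scaling alternatives the lowest median was 0.45, but a scaling moves every gene alike. The median of all tested genes lay between -0.05 with DESeq2 size factors and 0.04 without mitochondrial genes. Shifts of that size could not have removed the 4 medians, so the 0.45 follows from the library factors and is no further test. Lower cellular sterol would lower LXR targets, and it was fixed beforehand that ABCA1 and MYLIP not being lower would speak against it. Both were higher, with a mean log2 ratio of 0.72, so that criterion was met. Adding ABCG1, 19.2-fold lower and left out beforehand because its value had been seen, gives -0.94, through ABCG1 alone. With 2 genes against 1, lower sterol is not decided. A different growth state of the dish cannot be told apart from DEHP, because each condition is 1 culture and the G2 and mitosis median of 0.79 has no second control culture beside it. An effect of DEHP itself stays open and untested.

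Cytosolic ribosomal protein mRNAs were lower, with a median of -0.43. Random lists matched on mean count, GC content and length had a median of -0.12 (95% of them between -0.28 and 0.01), and the list lay at percentile 0.0 among them. GC content and length so measured account for part of the shift at most. They are those of each gene's longest transcript, which need not be the expressed one, so a bias from shorter expressed transcripts stays open. Scaling without mitochondrial genes moved every gene alike, and the median of all tested genes became 0.04. The list median of -0.39 under it follows from that shift and is no further test. Through the scaling alone, the larger mitochondrial share of the DEHP library thus accounts for little of the -0.43. Growth state, culture and DEHP stay open, as the design confounds them.

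The libraries differed by more than 8-fold at 70 genes, 27 higher and 43 lower. Counting error alone gave a mean of 0.0 such genes, which argues against it. Of 13 fibroblast, 18 immune and 12 endothelial markers, only 5, 2 and 4 reached a mean scaled count of 30, and the rest lay below it. At most 1 tested member of each list was 2-fold or more higher in the same library. The markers thus show no shared rise in 1 library, but so few leave a smaller share of such RNA open. Copy number differences between the cultures were taken beforehand to shift the 10 nearest tested genes by 0.3 or more, and a median signed log2 ratio below 0.1 to speak against them. The median was 0.065, under the 0.1 fixed beforehand, and its bootstrap interval of 0.021 to 0.102 lies below 0.3. That interval, which was not part of the criterion, reaches just past 0.1, so the test is not taken to decide. The largest median of 236 windows of 10 Mb was 0.36, on chromosome 10 between 120 and 130 Mb, where FGFR2 and MKI67 lie. The next largest, 0.34, was on the same chromosome in the window that holds ANXA8L1. Copy number differences, including focal changes such as the run on chromosome 21, cultures of different passage or origin, and DEHP stay open.

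A hypothesis for FBXO32 and ERBB3, both known FOXO targets, is that FOXO factors may have been more active in the DEHP culture. Of 18 other FOXO target genes listed before their values were seen, 16 had a ratio above 1, with a median log2 ratio of 0.43 at percentile 100 of matched random lists. CITED2 (1.09), KLHL24 (0.93) and BCL6 (0.88) were highest. IRS2 (-0.68) and FOXO1 (-0.37) went the other way, as did CDKN1A, which FOXO factors can also activate. The test rests on 1 library per condition, and other regulators of these genes were not tested. FBXO32 (chromosome 8, 123497889 to 123541206) also lies close to KLHL38 (123645527 to 123652950), on the same strand. KLHL38 was 18.6-fold higher, from 13 and 223 counts. A cause local to FBXO32 and KLHL38 was not tested and stays open beside FOXO activity for FBXO32.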
